A study of Mus musculus with 6 samples.

How the data were processed

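Bulk RNA was sequenced from the subventricular zone (SVZ), the stem cell niche along the lateral ventricle of the mouse brain, in 3 wild-type (WT) libraries and 3 libraries labelled as homozygous for a deletion of Zhx2 (KO). Groups and replicate numbers were taken from the sample titles. The genotype tags of KO 2 and KO 3 read ZHX3 KO and ZHX4 KO, while their titles and the study's design text name Zhx2. The Zhx family list used below holds no gene of the name Zhx4. The labels do not say that the libraries came from separate animals, so p-values measure only the spread between these libraries, which may be technical.

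The deposited table gives estimated counts for 61481 RefSeq transcripts in each library, per the file headers and the values. It also gives FPKM per transcript, scaled by the authors to transcript length and library total, judged from the deposited values, and the authors' group means; neither was used in a test. The genome build was mm10 and limma 3.40.6 was among the tools, per the submitters' processing notes. The aligner, the quantification tool and the annotation release are not given in the sources used here.

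Estimated counts were summed per NCBI gene number, giving 18614 genes, and rounded to whole numbers. Symbols came from the RefSeq gene table of assembly GRCm38.p6, which named 18489 of them. The 125 genes without a symbol held between 0.104% and 0.140% of a library's counts. Coordinates are those of mm10, the same sequence as that assembly. Libraries held between 17037152 and 17685906 counts, so that 3 counts, the floor for a gene not seen, correspond to between 0.17 and 0.176 CPM; this covers counting error only. No pair of libraries in a group agreed within sampling noise: the chi-square statistic per degree of freedom was between 21.7 and 95.4.

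Genes were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr with its minimum count of 10, trended and robust quasi-likelihood F test, group as the only term, two-sided), and p-values were adjusted by the Benjamini-Hochberg method over the 15126 genes kept. The threshold was an adjusted p of 0.05. Levels are TMM-scaled CPM, given as mean ± SD. The standard error of a log2 fold change was derived from the fold change and the F statistic. Fold changes are the KO-labelled libraries minus WT.

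Before the data were examined, 29 gene lists were fixed: pathways that the study's title names, cell types found in or near the SVZ, processes, quality markers and the neighbours of Zhx2. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 26 lists that qualified. Of these, 1 that did not pass is not reported here. Camera with an estimated correlation and fry were run beside it. Zhx2 was left out of every list test. Older symbols in the lists were replaced by current ones for 3 genes. In a first run H19, which has no row of its own, was matched by mistake to Nckap1, which carries H19 as an older name. That match gave the list of liver targets 3 tested members and made it the 27th list tested. It was removed after the results had been seen. Its removal moved Wnt pathway components and Blood from an adjusted p of 0.0506 to 0.0487, and the number of lists past the threshold from 5 to 7.

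The genes named were set by a rule fixed beforehand. It takes Zhx2, Zhx1, Zhx3 and Celsr1. It takes up to 10 genes per direction among those past the threshold with a mean of at least 1 CPM in one group and no overlap between groups, without Zhx2 and predicted loci. Where fewer than 5 pass, it takes the 5 with the smallest p in that direction, reported as not past the threshold. It takes up to 3 members with the smallest p from each list. Of this last part, the text names members of the study's lists, of lists past the threshold, of lists with a member past it when adjusted over the list alone, and of lists too small to test; this narrowing was made after the results were seen. Genes named outside the rule are marked as such, except Ttr, Celsr2, Celsr3, Ddx3y and Kdm5d, which also fall outside it.

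The procedure was tested on simulated counts for the same 15126 genes, drawn from the real means, spreads and library sizes. In it 200 genes were changed in 3 libraries against 3. They were picked only from genes with high mean counts, so the shares recovered do not cover genes with low counts. With edgeR, 4.48% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 93.9% of those changed 4-fold were recovered, and 5.61% of calls were unchanged genes. With DESeq2 1.42.0 these shares were 13.4%, 82.1% and 97.0%, and 29.7% of calls were unchanged genes. With limma-voom they were 2.99%, 40.3% and 89.4%, with 5.38%. These shares do not carry over to the real libraries. There edgeR did not call any choroid plexus list member, though their median log2 fold change was -5.18.

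The alternatives set beforehand were DESeq2 size factors or upper quartile scaling in edgeR, no filter, a filter of 5 CPM in 3 libraries, DESeq2's Wald test, limma-voom, a replicate block, each library left out in turn, KO 1 alone against WT, a threshold of 0.1, and camera with an estimated correlation. Alternatives planned for values other than counts did not apply. The fit of KO 1 alone takes its spread from the WT libraries only. Added after the data were seen were the striatal or choroid plexus list mean as a covariate, edgeR without the robust option, choroid plexus genes left out of other lists, and the mistaken match of H19. Figures were drawn with matplotlib 3.10.9. Mitochondrially encoded genes and Xist were not analysed here.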

Results

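RNA from the SVZ of wild-type mice and of mice labelled as lacking Zhx2, a zinc finger and homeobox transcriptional repressor, was compared in 3 libraries per group. Total estimated counts were similar, from 17037152 in WT 2 to 17685906 in WT 1, and between 17181 and 17422 genes had at least 1 count in each library. The first principal component, with 37.4% of the variance, placed the 3 WT libraries on one side and the 3 KO-labelled libraries on the other. The second, with 28.9%, set WT 2 apart.

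Zhx2, the gene that the deletion targets, was not lower in the libraries labelled KO. Its estimated counts were 735, 675 and 659 in WT 1 to 3 and 1139, 1004 and 959 in KO 1 to 3. Its level was 39.5 ± 1.17 CPM in WT and 60.4 ± 5.84 CPM in KO-labelled libraries (SD, n = 3), a log2 fold change of 0.61 (SE 0.10) that did not pass the threshold in edgeR (adjusted p = 0.163). DESeq2 gave an adjusted p of 0.00142 and also called Zhx2 in each of the 6 fits with a single library left out (adjusted p between 0.00160 and 0.0290). Over 17 alternatives the adjusted p ranged from 0.00142 to 0.9996. All 3 KO-labelled libraries lay above all 3 WT libraries, and the exact permutation p was 0.1, the smallest that 3 against 3 allows (two-sided). Zhx2 (NCBI gene 387609) lies on chromosome 15 of mm10 from 57694667 to 57839832 on the plus strand. Its coding sequence is in exon 3, from 57821237 to 57823744. The table splits its counts over 3 RefSeq transcripts. The main one had 656, 629 and 451 counts in WT and 1106, 971 and 959 in KO-labelled libraries; another had 49.1, 0 and 184 in WT and 0 in each KO-labelled library. These are estimated splits between overlapping transcripts. Because Zhx2 goes against the label, every direction given here is that of the libraries labelled KO against those labelled WT.

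Its paralogs Zhx1 and Zhx3 were not lost in any library, and the genotype tag of KO 2 names ZHX3. Zhx2 was not lost in any library either, so transcript levels do not show which gene, if any, a library lacks. Zhx1 was at 83.8 ± 11.4 CPM in WT and 74.7 ± 8.64 CPM in KO-labelled libraries, and Zhx3 at 29.9 ± 3.72 and 23.6 ± 3.86 CPM (SD, n = 3). Zhx3 in KO 2 was at 19.98 CPM, against 23.1 in KO 1 and 27.7 in KO 3. Neither paralog passed in edgeR, with log2 fold changes of -0.17 (SE 0.14, adjusted p = 0.752) and -0.34 (SE 0.16, adjusted p = 0.583).

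**Figure D1:**
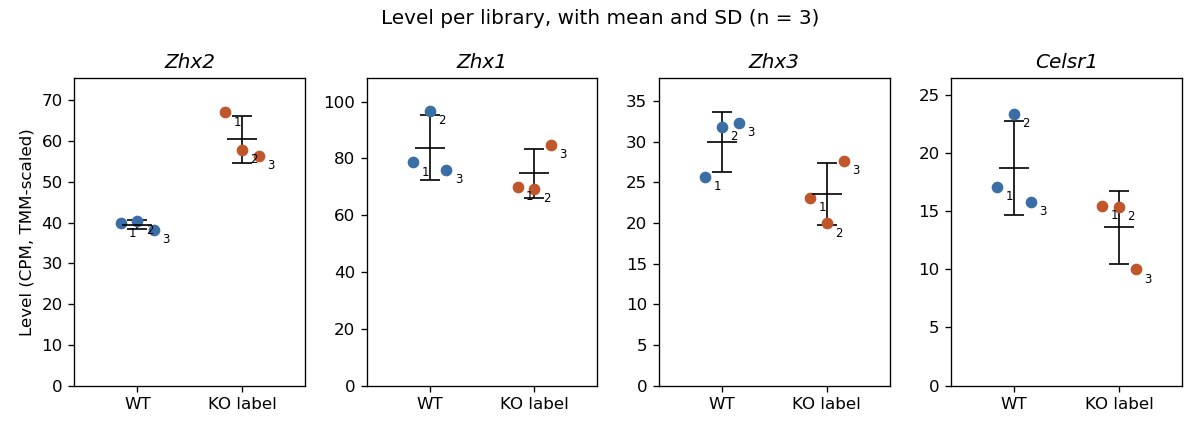
Levels of Zhx2, Zhx1, Zhx3 and Celsr1 in CPM (vertical axes, from 0) in the 3 WT and 3 KO-labelled libraries; points are libraries with their replicate number, and bars are the mean and SD. Zhx2 lies between 38.2 and 40.5 CPM in WT and between 56.3 and 67.1 CPM in KO-labelled libraries.

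Across all genes, the 5 genes with the smallest p among those lower in the libraries labelled KO were Mfrp, Slc4a5, F5, Kcne2 and Kl, of which all but Mfrp are on the fixed choroid plexus list. Mfrp was at 74.6 ± 41.3 CPM in WT and 0.913 ± 0.209 CPM in KO-labelled libraries. The bicarbonate transporter gene Slc4a5 was at 81.7 ± 47.4 and 0.426 ± 0.293 CPM, the coagulation factor gene F5 at 140 ± 72.9 and 1.74 ± 1.11 CPM, the potassium channel subunit gene Kcne2 at 51.9 ± 29.8 and 0.426 ± 0.281 CPM, and Kl, which encodes klotho, at 351 ± 198 and 6.70 ± 2.55 CPM (SD, n = 3). In the other direction, the genes with the smallest p, with Zhx2, which comes next after Lxn, set aside by the rule, were Lxn (log2 fold change 0.65, SE 0.09), Zfp428 (0.56, SE 0.11), Nrros (0.83, SE 0.18), Gls2 (0.57, SE 0.13) and Nat8f3 (0.77, SE 0.17).

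None of these passed in edgeR, which called 0 of 15126 genes (lowest adjusted p = 0.144), with 1372 at an unadjusted p under 0.05 (406 higher and 966 lower) where chance gives 756. Limma-voom also called 0, and DESeq2 called 311, of which 6 were higher and 305 lower in the libraries labelled KO. The 6 higher genes were Lxn, Zhx2, Zfp428, Nrros, Nat8f3 and Uchl1; Uchl1 falls outside the naming rule and was named after its values were seen. Groups did not overlap in 2532 genes, 16.7% of those tested, where chance gives 10%. Without WT 3, edgeR called 137 genes, all lower. With single libraries left out, DESeq2 called between 139 genes (without WT 1) and 451 (without WT 3), and the number higher was 106 of 348 without WT 2, 40 without KO 3, 28 without WT 3, 12 without KO 1, 5 without WT 1 and 4 without KO 2. In the simulation 29.7% of DESeq2's calls were unchanged genes, a share that does not carry over to the real libraries.

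Markers of the choroid plexus, the epithelium that secretes cerebrospinal fluid, fell together. All 20 tested members were lower in the libraries labelled KO, with a median log2 fold change of -5.18, and 20 of 20 passed when adjusted over the list alone in edgeR, against 0 over all genes. The list passed in camera (adjusted p = 1.45e-34), and the call was lost with an estimated correlation (adjusted p = 0.375 with an estimated correlation). The list took 2.44%, 1.79% and 0.552% of counts in WT 1 to 3, and 0.0482%, 0.0558% and 0.0342% in KO 1 to 3. In KO 1 to 3 most of that share was the list member Enpp2, at 427, 329 and 241 CPM. Ttr, the transthyretin gene and the gene with the most counts in WT 1 and WT 2, had 283352, 177765 and 54011 counts in WT and 221, 1988 and 232 in KO-labelled libraries.

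Ependymal and motile cilium genes were lower as well. Of 28 members, 26 had a negative log2 fold change, the median was -0.79, and 16 fell when adjusted over the list alone in edgeR (0 over all genes). Cfap44 was at 27.6 ± 5.37 CPM in WT and 9.84 ± 1.15 CPM in KO-labelled libraries, Rsph4a at 22.4 ± 4.32 and 10.2 ± 1.15 CPM, and Hydin at 16.4 ± 3.14 and 7.15 ± 1.18 CPM (SD, n = 3). The list passed in camera (adjusted p = 1.19e-16), but not with an estimated correlation (adjusted p = 0.375 with an estimated correlation). Choroid plexus markers moved in the same direction in the same libraries.

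Microglia markers were higher in the libraries labelled KO. With the 6 libraries, all 18 members had a positive log2 fold change, with a median of 0.31, and the list passed in camera (adjusted p = 7.54e-06), but not with an estimated correlation (adjusted p = 0.516 with an estimated correlation). No single member passed in edgeR over all genes or adjusted over the list alone, while 6 had an unadjusted p under 0.05, and DESeq2 and limma-voom called none. Without KO 3, 4 members passed over the list alone and DESeq2 called 3; without WT 1 the median was 0.19. WT 1 had the lowest mean log2 level of these markers (4.44) and of striatal markers (5.19), and the highest share of choroid plexus markers. With the striatal list mean as a covariate the median was 0.19 (camera adjusted p = 0.00296). The complement gene C1qc was at 45.1 ± 2.08 CPM in WT and 61.8 ± 9.19 CPM in KO-labelled libraries, Trem2 at 11.8 ± 1.46 and 16.9 ± 2.34 CPM, and Ctss at 64.9 ± 2.91 and 80.9 ± 6.90 CPM (SD, n = 3).

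Striatal projection neuron, cell cycle and blood genes also passed in camera. Each call depended on single libraries and was also lost under other settings. The striatal call was kept in 10 of 16 alternatives, its own mean as a covariate left out because it removes the list's signal. Those of cell cycle and blood genes were kept in 10 and 8 of 17. Each count of kept calls includes edgeR without the robust option, which leaves camera's input unchanged. Striatal markers had a median log2 fold change of 0.26 (camera adjusted p = 0.0372; adjusted p = 0.902 with an estimated correlation). Drd2 was at 152 ± 147 CPM in WT and 216 ± 46.0 CPM in KO-labelled libraries, Meis2 at 298 ± 141 and 362 ± 52.4 CPM, and Isl1 at 18.1 ± 0.659 and 15.7 ± 4.12 CPM (SD, n = 3). The mean log2 level of the striatal list was 5.19, 8.53 and 7.11 in WT 1 to 3 and 7.55, 7.86 and 7.95 in KO 1 to 3. Camera works on such log2 levels, while the median of 0.26 is of edgeR's fold changes, so they need not match in size. The median was 0.96 with limma-voom (adjusted p = 0.0248), 0.98 under the replicate block (0.00245) and 1.53 without WT 2 (4.09e-10). Without WT 1 its median was -0.20, and the call was also lost without WT 3 (adjusted p = 0.0683), KO 2 (0.0709) or KO 3 (0.129), by camera. The choroid plexus covariate lost the striatal call too (camera adjusted p = 0.885), and with KO 1 alone against WT the striatal median was -0.025. Cell cycle genes had a median of 0.16 (camera adjusted p = 0.0413; adjusted p = 0.902 with an estimated correlation). Without WT 1 that median was -0.015, and the call was lost without WT 3 (adjusted p = 0.262) or KO 2 (0.149), with the filter of 5 CPM (0.207) and with DESeq2 (0.0671) too, while without WT 2 the median was 0.44 (4.09e-10). Tyms, Plk1 and Ccnb2 had log2 fold changes of 0.33, 0.37 and 0.77. Blood genes had a median of 0.40 over 5 members (camera adjusted p = 0.0487; adjusted p = 0.718 with an estimated correlation). The members with the smallest p were the globin genes Hba-a2 (0.51), Hbb-bs (0.44) and Hba-a1 (0.33). Their median was between 0.10 (without WT 2) and 0.63 (without WT 3) with single libraries left out. That call was lost without WT 2 (adjusted p = 0.438), KO 1 (0.126), KO 2 (0.0709) or KO 3 (0.0509), with DESeq2 size factors (0.0542), upper quartile scaling (0.0541), the filter of 5 CPM (0.0681) and DESeq2 (0.0530). No member of these 3 lists passed over the list alone.

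**Figure D2:**
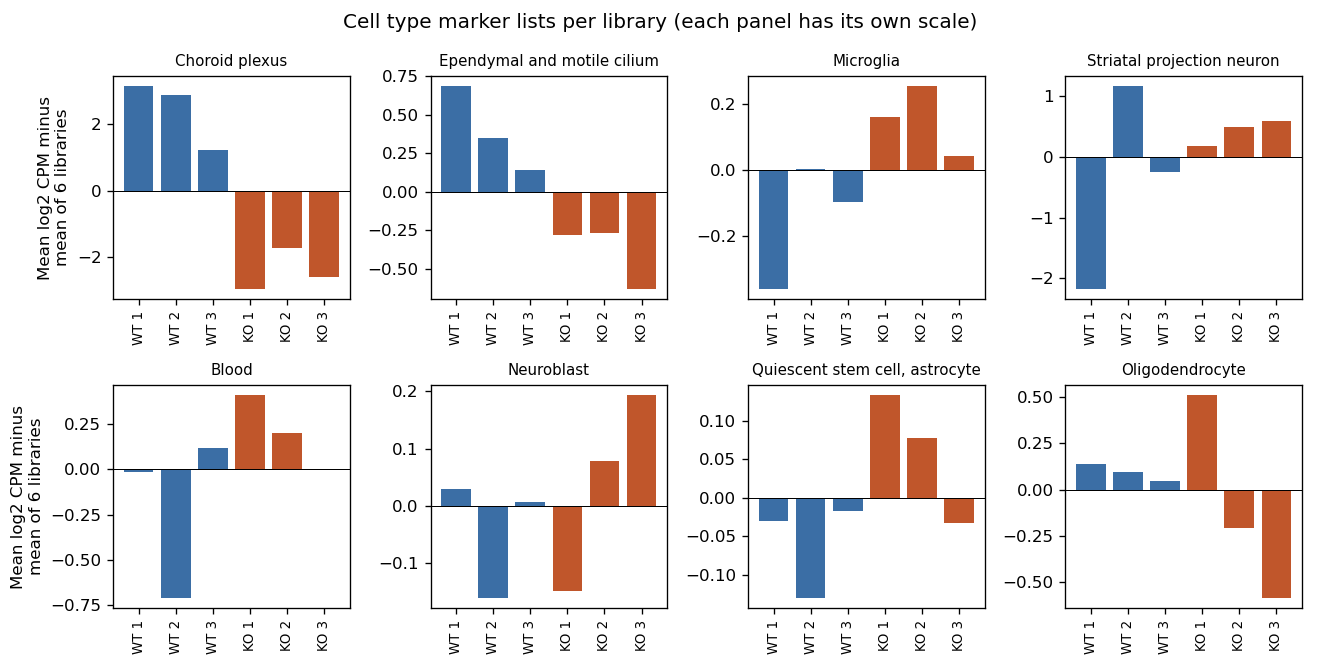
Mean log2 CPM of 8 cell type marker lists in each library, drawn as the difference from the mean of the 6 libraries (vertical axes, each panel with its own scale; blue WT, orange KO-labelled). Choroid plexus markers separate the groups by the widest margin of these lists, and striatal markers are lowest in WT 1 and highest in WT 2.

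The study's title names CELSR1 and Wnt, which the next comparisons address. Celsr1, a planar cell polarity cadherin gene (NCBI gene 12614, chromosome 15 of mm10, 85898758 to 86034223, minus strand), was at 18.7 ± 4.04 CPM in WT and 13.6 ± 3.13 CPM in KO-labelled libraries (SD, n = 3). Its log2 fold change of -0.46 (SE 0.23) did not pass in edgeR (adjusted p = 0.603). The level in every KO-labelled library was below that in every WT library, with an exact permutation p of 0.1. WT 3 was the lowest WT library, at 15.8 CPM, as for the choroid plexus markers, against 15.4 CPM in the highest KO-labelled library. The log2 fold change was between -0.57 and -0.28 with single libraries left out. With the choroid plexus covariate, which lies almost wholly between the groups, it was 0.28 (SE 0.83). Celsr2 and Celsr3 had log2 fold changes of 0.03 and 0.00.

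The planar cell polarity list did not pass in camera (median log2 fold change -0.12, adjusted p = 0.0694), and 0 of its 26 members passed in edgeR over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05 and none called by DESeq2 or limma-voom. Ror1 was at 4.79 ± 1.03 CPM in WT and 2.39 ± 0.753 CPM in KO-labelled libraries, Fzd6 at 13.4 ± 2.65 and 9.58 ± 0.785 CPM, and Daam1 at 92.6 ± 1.598 and 72.2 ± 13.2 CPM (SD, n = 3).

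Of 34 Wnt pathway components, 22 had a negative log2 fold change (median -0.15), and 5 receptor and secretion genes fell when adjusted over the list alone in edgeR, with 0 over all genes. The receptor genes Lrp5 (log2 fold change -0.77, SE 0.14), Fzd7 (-1.75, SE 0.35) and Fzd4 (-1.20, SE 0.30) were among them, as were Lrp6 (-0.76) and Wls (-0.59), the last 2 named after their values were seen. The count of 5 was 6 without WT 3, 1 without WT 1 or KO 2, and 0 without WT 2, KO 1 or KO 3, and the list's median was -0.067 without WT 1. Choroid plexus markers moved in the same direction: WT 3, the WT library with the lowest share of them, was the lowest WT library for Lrp5, Fzd7 and Fzd4. The list passed in camera (adjusted p = 0.0487; adjusted p = 0.375 with an estimated correlation). That call was kept in 5 of 17 alternatives. Among the 5 is edgeR without the robust option, which leaves camera's input unchanged and could not lose it. The call was lost under DESeq2 size factors (camera adjusted p = 0.0587), upper quartile scaling (0.0541), no filter (0.0569), DESeq2 (0.0526) and the replicate block (0.0616). It was also lost with the striatal (0.0525) or choroid plexus (0.885) covariate, and without WT 2 (0.0977), WT 3 (0.106), KO 1 (0.0609) or KO 3 (0.163). The fit of KO 1 alone against WT, with a list median of -0.28, did not keep it either. With the earlier match of H19 the list did not pass (0.0506). Over the 17 alternatives the camera adjusted p ranged from 0.0307 to 0.885. Canonical Wnt targets did not pass (camera adjusted p = 0.879); their median log2 fold change was 0.10, while the mean and the test were negative. Prox1 (-0.90, SE 0.27), Lef1 (-0.66, SE 0.24) and Znrf3 (-0.34, SE 0.14) had the smallest p.

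**Figure D3:**
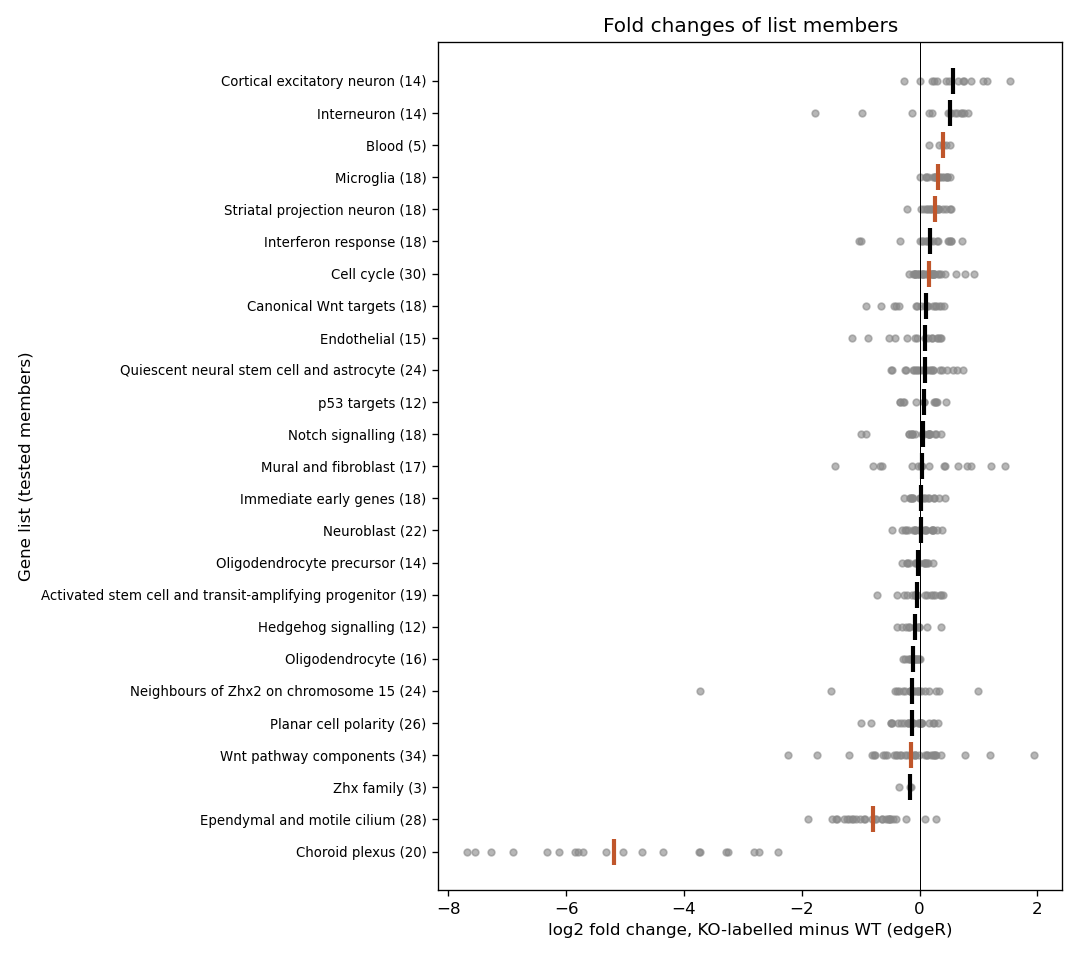
Log2 fold changes of the members of 25 gene lists (horizontal axis, KO-labelled minus WT; grey points are genes, upright marks are medians, orange where camera with the preset correlation passed). Choroid plexus members lie between -7.69 and -2.41.

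A few members of other lists fell when adjusted over the list alone, while their lists did not pass in camera. Notch2 was at 61.4 ± 12.3 CPM in WT and 30.6 ± 1.25 CPM in KO-labelled libraries, and Hey2, a Notch target gene, at 11.5 ± 1.47 and 6.12 ± 0.449 CPM (SD, n = 3); these 2 of 18 Notch genes fell, and Hes5 had a log2 fold change of 0.26. Ocln, a tight junction gene (log2 fold change -1.15, SE 0.20), and Kdr, a VEGF receptor gene (-0.88, SE 0.22), were the 2 of 15 endothelial list members that fell, and Slco1a4 had -0.42. The endothelial count was 4 without WT 3, 1 without WT 1 or WT 2, and 0 without KO 1, KO 2 or KO 3. Of 24 neighbours of Zhx2 on chromosome 15, Enpp2 (-3.73, SE 0.52) and Sntb1 (-1.50, SE 0.32) fell, and Deptor had -0.41; Enpp2 is also on the choroid plexus list. The count of neighbours was 1 without WT 1, WT 2, WT 3 or KO 1, 0 without KO 2 and 2 without KO 3. WT 3 was the lowest WT library for Notch2, Hey2, Ocln, Kdr, Enpp2 and Sntb1, as for the choroid plexus markers. None of these genes passed over all genes in edgeR.

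The remaining lists had camera adjusted p values between 0.0694, that of planar cell polarity, and 0.879, that of canonical Wnt targets. Median log2 fold changes were 0.08 for quiescent stem cell and astrocyte genes, -0.05 for activated stem cell and transit-amplifying progenitor genes and 0.02 for neuroblast genes. They were 0.57 for cortical excitatory neurons, 0.52 for interneurons, -0.11 for oligodendrocytes, -0.03 for their precursors and 0.04 for mural cells and fibroblasts. They were -0.08 for hedgehog signalling, 0.17 for the interferon response, 0.02 for immediate early genes, 0.07 for p53 targets, 0.05 for Notch signalling, 0.09 for endothelial cells, -0.12 for the neighbours of Zhx2 and -0.17 for the Zhx family. With single libraries left out, the interneuron median was between 0.15 (without KO 3) and 0.61 (without WT 3). Some of these lists passed with a library left out: oligodendrocytes without KO 1 (median -0.48, camera adjusted p = 1.05e-11, 4 members lower over the list alone), interneurons without KO 1 (0.24, 0.00425, 3 members higher), cortical excitatory neurons without WT 3 (1.21, 0.0154) or KO 3 (0.98, 0.0436), interferon genes without KO 2 (-0.18, 0.00918) and the neighbours of Zhx2 without KO 1 (-0.14, 0.0434). The mean and the test were negative for Notch and endothelial genes, and the test was positive for activated stem cell genes. Of the liver targets of Zhx2, Lpl (-0.46, SE 0.82) and Gpc3 (-0.11, SE 0.60) were tested, as were the Y-linked genes Uty (-0.39, SE 0.34) and Eif2s3y (-0.06, SE 0.25); none passed. The Y-linked genes Ddx3y and Kdm5d had between 0 and 4 counts in every library, so the counts of Uty and Eif2s3y, at means near 2 CPM, are not read as expression from the Y chromosome. The 5 lists that passed fry for changes in either direction were choroid plexus, ependymal, Notch, Wnt components and the neighbours of Zhx2, and none passed its test for one direction (lowest adjusted p = 0.0632).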

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

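The covariates, the left-out robust option, choroid plexus genes left out of other lists and the match of H19 were chosen after the data were seen; the other alternatives were planned. Of 1168 values of 69 genes and lists under alternatives, Zhx2 and Celsr1 included, 1101 kept their direction and 67 reversed. For lists, edgeR without the robust option leaves camera's input unchanged, so it could not alter a call. The count of genes past the threshold, 0 by edgeR with 1372 at an unadjusted p under 0.05, was 311 with DESeq2, 0 with limma-voom and between 0 and 137 with single libraries left out, the highest without WT 3; 133 of those 137 are among DESeq2's 311. For members of the fixed lists the count was 43 with DESeq2 and between 0 and 22 with single libraries left out. The number of lists past the threshold, 7, was 0 with an estimated correlation, 4 on DESeq2's transformed values, 4 with the striatal covariate (which removes the striatal list's own signal), 5 with H19 matched to Nckap1, and between 5 and 8 with single libraries left out. Zhx2 passed with DESeq2 (log2 fold change 0.60) and in no other of its 17 alternatives, and DESeq2 kept that call with each library left out; with single libraries left out it was between 0.53 and 0.66, and Celsr1 between -0.57 and -0.28. The replicate numbers did not pair the libraries (correlations of -0.16, -0.07 and -0.04 for numbers 1 to 3), and the fit with the replicate block called 0 genes by edgeR, with 1018 at an unadjusted p under 0.05, and 6 lists. The cause was not tested for any of these changes.

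The following are log2 fold changes, or list medians, that reversed. With the filter of 5 CPM, canonical Wnt targets were at -0.057. With limma-voom, Lpl was at 0.30, Gpc3 at 0.14 and activated stem cell genes at 0.096; under the block these were 0.24, 0.13 and 0.087. With KO 1 alone, neuroblast genes were at -0.26, striatal -0.025, interneuron -0.48, oligodendrocyte 0.41, oligodendrocyte precursor 0.098, endothelial -0.20, mural and fibroblast -0.22, Notch -0.030 and interferon genes -0.12. With the striatal covariate, Gpc3 was at 0.74, cell cycle -0.018, endothelial -0.054, Notch -0.074 and immediate early genes -0.030. The choroid plexus covariate lay 92.2% between the groups, so its fit leaves little to estimate the group from: the SE of Zhx2 went from 0.10 to 0.42 and that of Celsr1 from 0.23 to 0.83. In it Celsr1 was at 0.28, Zhx1 0.094, Lpl 1.24, Gpc3 0.48, Ror1 0.49, Fzd6 0.090, Lef1 0.29, Lrp5 0.13, Fzd4 0.60, Isl1 0.19, Ocln 0.054, Kdr 0.34, Slco1a4 0.32, Notch2 0.15, Uty 0.48, Eif2s3y 0.14, Hba-a2 -0.63, Hbb-bs -0.74 and Hba-a1 -0.65. The lists that reversed in it were canonical Wnt targets (-0.24), activated stem cell (0.019), ependymal (0.29), cortical excitatory (-4.35), interneuron (-0.37), blood (-0.63), Notch (-0.30), immediate early (-0.99) and p53 genes (-0.17). Lists that passed camera in this fit include cortical excitatory (adjusted p = 7.59e-05) and immediate early genes (0.00449), both reversed, and cell cycle genes (0.00449).

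With single libraries left out, ranges that crossed 0 were Lpl -0.96 to 0.997, Gpc3 -0.57 to 0.43, Eif2s3y -0.18 to 0.051, canonical Wnt targets -0.031 to 0.11, cell cycle -0.015 to 0.44, neuroblast -0.093 to 0.13, striatal -0.20 to 1.53, cortical excitatory -0.60 to 1.21, oligodendrocyte -0.48 to 0.12, oligodendrocyte precursor -0.13 to 0.038, endothelial -0.13 to 0.19, mural and fibroblast -0.078 to 0.22, Notch -0.091 to 0.094, interferon -0.18 to 0.37 and immediate early genes -0.095 to 0.25. The choroid plexus, ependymal and microglia lists kept their direction and passed in all alternatives with the preset correlation except the choroid plexus covariate, which removes the choroid plexus list's own signal.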

Other observations

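The test of a genotype effect on choroid plexus markers and the 3 tests on Zhx2 were chosen after the result had been seen. The others were written before, but that of choroid plexus tissue for ependymal and cilium genes was not read by its written bound.

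Genes that DESeq2 called lower in the libraries labelled KO, outside the fixed lists and named here after their values were seen, include the dorsal midline regulator Lmx1a (log2 fold change -5.22, DESeq2 adjusted p = 7.4e-05), the transcription factor Nr2f2 (-1.55, adjusted p = 9.13e-07) and the dynein gene Dnah6 (-1.77, adjusted p = 2.28e-08). None passed in edgeR.

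Choroid plexus markers together were at least 9.89 times as large a share of counts in every WT library as in any KO-labelled library. Most of the share in the KO-labelled libraries came from 1 member, Enpp2, at 332 ± 93.1 CPM there. Ttr took 0.315% of counts in WT 3 and 0.00127%, 0.0115% and 0.00136% in KO 1 to 3. The markers also differed within the WT group: the median log2 ratio of WT 1 to WT 3 was 1.98. The ratio was nearly the same for every marker, from 1.54 to 2.29 (median absolute deviation 0.203). A candidate explanation for the lower levels in the libraries labelled KO is thus the amount of choroid plexus taken in each dissection. Between the groups the markers' log2 fold changes were less even, from -7.69 to -2.41, and evenness there was not tested. Among 285 genes outside the list that DESeq2 called lower, WT 3 was the lowest of the WT libraries for 91.6%, against 23.4% of all tested genes. WT 3 has the fewest choroid plexus counts of the WT libraries, so the same explanation may cover most of them. WT 3 also lay nearest the KO-labelled libraries on the first principal component (-8.77, against -56.6 in WT 1 and -16.1 in WT 2). Any other difference graded in that order would give such a share. A genotype effect on these genes or on the amount of choroid plexus cannot be told apart from the amount taken in dissection. No library of either genotype is known to hold the same parts.

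For ependymal and cilium genes, the excess of WT 3 over the KO-labelled mean was a median of 0.449 of the excess of WT 1 and WT 2, above the 90th percentile of 0.292 for choroid plexus markers. The bootstrap 95% interval of that share (0.305 to 0.609) lay above this percentile as well. By the bound set beforehand, this counts against choroid plexus tissue as the source. The question was left open all the same, which departs from that bound. The share rests on WT 3 alone, and the interval is over genes with an estimated correlation of 0.497. In the other direction, WT 3 was the lowest WT library for 60.7% of the members, against 23.4% of all tested genes. A different amount of ependymal tissue and a genotype effect stay open too: the median absolute deviation of the members' log2 fold changes was 0.312, between the bounds set for it.

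Zhx2 was higher in the libraries labelled KO, against the label. Dilution of the WT libraries by tissue without Zhx2 would put genes of the resident cell types higher by about as much as Zhx2 (log2 fold change 0.61). The median over 93 members of the stem cell, progenitor, neuroblast and oligodendrocyte lineage lists was -0.020 (SD 0.25). TMM scaling sets the bulk of genes near 0 (median of all genes 0.018), so a median near 0 is not evidence by itself. The scaling shifts Zhx2 and these genes alike and leaves the gap between them. Only that gap argues against dilution, and for those cell types only. The neuron and microglia lists were left out, with medians of 0.26 (striatal), 0.57 (cortical excitatory), 0.52 (interneuron) and 0.31 (microglia). Which cell types hold Zhx2 was not analysed here. Reads moved from the paralogs stay open: Zhx1 and Zhx3 together lost 15.5 CPM (SE 10.4), 0.74 of the gain of Zhx2 of 20.9 CPM (SE 3.44). The lower group held 65.4% of the higher group's level, so neither group lacked the transcript. A deletion that leaves the transcript in place stays possible in either group, so swapped labels cannot be told apart from correct ones. Whether any library carries the deletion cannot be told from these levels either. Which part of Zhx2 the deletion removes was not analysed here.

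Within 5 Mb of Zhx2, 6 of 34 tested genes (17.6%), Zhx2 left out, had an unadjusted p under 0.05, against 9.04% of other genes (Fisher's exact p = 0.122, two-sided), so flanking DNA of another strain was neither shown nor excluded. Among the 6 were Enpp2, which is on the choroid plexus list, and Sntb1, for which WT 3 was also the lowest WT library. The share was not computed without them. The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. The real split gave 0 genes in edgeR (1372 at an unadjusted p under 0.05, and 311 by DESeq2), and all 10 splits gave as many, the highest of the others 2. Any split reaches a count of 0, so that comparison could not have come out otherwise. With DESeq2 the real split gave 311 genes and the highest of the others 58, so 1 split gave as many. For gene lists in camera the real split gave 7 and the highest of the others 9, and 6 splits gave as many.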
